A study of Arabidopsis thaliana and Brassica oleracea with 14 samples.

How the data were processed

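Leaf RNA of Arabidopsis thaliana (accession Col-0) and Brassica oleracea var. alboglabra (line A12DH) was measured on macroarrays, which are membranes spotted with DNA probes and hybridised with radioactively labelled cDNA. Per the labels, plants were 4 weeks old and grew under a 16 h photoperiod. Drought plants received no water for 5 days, until the relative water content of the leaves averaged 45% with a spread of 15, and control plants were watered. RNA was extracted from leaves of 5 plants at a time and pooled, and 10 µg was labelled with 33P, per the labels. Each of the 14 arrays carries 1 labelled sample. There were 4 control arrays and 3 drought arrays of each species, and the sample titles set the groups. The design text speaks of biological replicates, but the labels do not tie each array to its own pool of plants, so the p-values measure the spread between these arrays, part of which may be technical.

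Per the file headers, the deposited files give for each of 768 positions (16 rows, A to P, of 48 columns) a total spot intensity, a background intensity, their difference as a volume, a normalized volume and a presence flag. The authors' volume intensity equalled total minus background, with negative differences set to 0, within a tolerance of 0.02 at all but 3 of 10752 spots. On A. thaliana drought replicate 2 the deposited background intensity was 0 at every spot. The normalized volume was the volume times 1 factor per array on a linear scale, and the deposited value table was identical to it. The medians of that table's columns were 62.5, 158, 13.1 and 25.7 for A. thaliana controls 1 to 4 and 35.7, 64.1 and 32.5 for A. thaliana drought 1 to 3. They were 70.8, 312, 35.5 and 51.3 for B. oleracea controls 1 to 4 and 28.0, 26.7 and 555 for B. oleracea drought 1 to 3. What the factor refers to stays unknown. The flag was not used, since the lowest flagged volume differed between arrays. The quantification software and its settings are not given in the sources used here.

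The label column of the files is empty, and the labels name 522 spotted features without their positions. No gene was therefore paired with a position, and results are given for positions. The gene lists chosen beforehand (PP2C phosphatases, abscisic acid signalling, dehydration markers, housekeeping genes and others), the leaf cell type markers, the naming of PP2C genes and the scaling to housekeeping genes could not be applied. The values themselves showed that columns 1 and 2, 3 and 4, and so on carry like signals, and each such position pair was treated as a duplicate of 1 probe. This left 384 position pairs, all tested, since no blank or control spot is named. A quality column holds the word spike at 2 of the 10752 spots over all arrays, which does not name a control position. In 96 pairs (even-lettered rows B to P, columns 25 to 48) the median agreement of the spots of a pair over the arrays was a Spearman correlation of 0.116. It was 0.306 in the odd-lettered rows at columns 25 to 48. At columns 1 to 24 it was 0.642 in the odd-lettered and 0.593 in the even-lettered rows. The block of the 96 pairs with low signal, called the low block, was used in place of blanks. It is not shown to be empty: P47/P48 was above its limit on 5 of the 6 drought arrays, and leaving that pair out of the block moved the drought difference in the share of pairs above it from 34.7 to 35.4 percentage points in B. oleracea and from 6.48 to 6.83 in A. thaliana. A pair counted as above it on an array when its total minus background exceeded the 95th percentile of the 96 pairs. Both choices were made after the data were seen. The 522 features of the labels were not reconciled with the 384 pairs, so pairs outside the low block may also be unspotted or hold more than 1 feature.

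Total intensities were corrected for background with the normexp model, with an offset of 17.7 units, set by a rule from the median total intensity of 177 units (the median divided by 10), put on the log2 scale and quantile normalized over the 14 arrays, and the spots of each pair were averaged. limma 3.58.1 in R 4.3.3 fitted the mean of each of the 4 groups with 1 shared estimate of the spread. The contrasts were drought against control within each species, the difference of these responses (B. oleracea minus A. thaliana) and B. oleracea against A. thaliana in control plants. limma's moderated test was adjusted by Benjamini-Hochberg over the 384 pairs, with a threshold of 0.05. These steps, the offset rule, the contrasts and the naming rule were fixed before the data were examined. Array measures were compared by 2-sided exact permutation tests over the 35 splits of 7 arrays. A fold change on this scale understates the change of dim spots, because of the offset.

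The naming rule asked for up to 10 pairs each way past the threshold in a drought comparison and, where fewer than 5 passed, the 5 with the smallest unadjusted p, and for 5 each way in the comparison of the species. Without gene names it allows at most 2 position pairs that are higher and 2 that are lower per comparison. Where a named pair was not above the low block on every array of the dimmer group, the fold is given only as a bound, a rule widened after the data were seen. Differences of the responses, the changes of P47/P48 and the value of A7/A8 with the background level as a block are given as fitted. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the lowest normalized level among pairs above the low block or the pair's own level, whichever was higher. It allows for dim signal but not for the spread between arrays, so it is not a lower confidence limit. In size, the 95% interval of the fitted log2 difference reached below the bound at G19/G20, M41/M42, A7/A8, M5/M6 and K15/K16. It stayed above the bound at A41/A42.

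The fit was tested on simulated data for the contrast in A. thaliana, in 10 runs of 384 pairs with 60 changed pairs each. It recovered 20.5% of 200 pairs with a log2 shift of 1, 89.0% of 200 with a shift of 2 and 97.5% of 200 with a shift of 3. Over the 10 runs it called 14 unchanged pairs in A. thaliana and 9 in B. oleracea, where no pair was changed. Simulated falls started 3 log2 units above the pair's level, with the pair's own fitted spread, and noise was independent between arrays. Some real bright pairs spread more widely (SD 1.90 at K15/K16 in A. thaliana controls), so the shares recovered may be too high for them. The number of arrays and the low signal over background limit the precision. Alternatives covered the background correction, the offset, the normalization, the value table, a filter on dim pairs, the variance model, a fit per species, the replicate number as a block, each spot on its own and leaving out each array. Others were added after the data were seen: the background level of the image as a block or held fixed, array weights, leaving out 2 arrays, a filter at the low block, the low block without P47/P48, and Pearson in place of Spearman correlations between spots. Figures were drawn with matplotlib 3.10.9.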

Results

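The series asks how drought changes leaf transcripts in A. thaliana and in its crop relative B. oleracea, with the genes of PP2C protein phosphatases, a family that includes negative regulators of abscisic acid signalling, in its title. The 14 arrays hold 384 position pairs, each a pair of adjacent spots read as 1 probe, and no gene name is attached to them here. Values are normalized signals on the log2 scale, given as mean ± SD over arrays, and the number of arrays limits their precision. A fold given as at least a value is a bound for dim signal and leaves out the spread between arrays.

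More position pairs gave a signal on arrays of droughted than of well-watered B. oleracea, though the difference did not pass after adjustment over the 8 array tests. Outside the low block, 288 pairs were compared with it. In B. oleracea, 28.0% ± 7.73 of these pairs (SD, n = 4) were above the low block on control arrays and 62.6% ± 12.1 (SD, n = 3) on drought arrays, with no overlap between the groups (exact permutation p = 0.0286, the smallest that 35 splits can give). In A. thaliana the shares were 40.3% ± 24.1 (SD, n = 4) and 46.8% ± 13 (SD, n = 3) (exact permutation p = 0.629), and without control replicate 3, which had 76.0%, the difference between them rose from 6.48 to 18.4 percentage points, while without drought replicate 1 it was -0.694. On every array of the group, 27 pairs were above the low block in B. oleracea controls and 123 in B. oleracea drought, against 38 in A. thaliana controls and 57 in A. thaliana drought, counts that favour drought because it has 3 arrays and controls 4. Over the sets of 3 control arrays the counts were 27 to 39 in B. oleracea and 39 to 55 in A. thaliana.

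The other array measures were compared between the groups in the same way, and none of their differences passed after adjustment. The Spearman correlation between the spots of a pair was 0.322 ± 0.0708 in B. oleracea controls (SD, n = 4) and 0.716 ± 0.127 under drought (SD, n = 3) (exact permutation p = 0.0286). As a Pearson correlation of normalized log2 values it was 0.772 ± 0.0549 (SD, n = 4) and 0.912 ± 0.0511 (SD, n = 3), a difference of 0.140 in place of 0.394. In A. thaliana the correlations were 0.458 ± 0.240 (SD, n = 4) and 0.748 ± 0.192 (SD, n = 3) (exact permutation p = 0.171). The drought value of 0.955 on replicate 2, the array with a background of 0, is not a measure of probe signal, since its spots correlated at 0.954 in the low block too, against 0.195 or less on the other arrays, and without it the difference between the groups fell from 0.290 to 0.187. The median signal over background was 1.70 ± 0.869 units in B. oleracea controls (SD, n = 4) and 8.30 ± 2.42 units under drought (SD, n = 3) (exact permutation p = 0.0286). It was 35.5 ± 45.4 units in A. thaliana controls (SD, n = 4) and 42.9 ± 38.5 units under drought (SD, n = 3) (exact permutation p = 0.771). The drought mean includes 83.7 units on replicate 2, which is its total signal, against 7.37 and 37.6 on replicates 1 and 3. The control mean includes 103 units on control 3, against 9.94 to 17.5 on the other controls, so the direction is not settled. The median background lay between 2202 and 2465 units on the A. thaliana controls and was 142, 0 and 2086 units on the 3 drought arrays (exact permutation p = 0.0286). On B. oleracea arrays it lay between 97.2 and 115 units in controls and was 101, 85.7 and 731 units under drought (exact permutation p = 0.400). After Benjamini-Hochberg adjustment over these 8 tests, the 4 smallest exact permutation p-values became 0.0571, so none of the 8 differences passed the threshold.

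**Figure D1:**
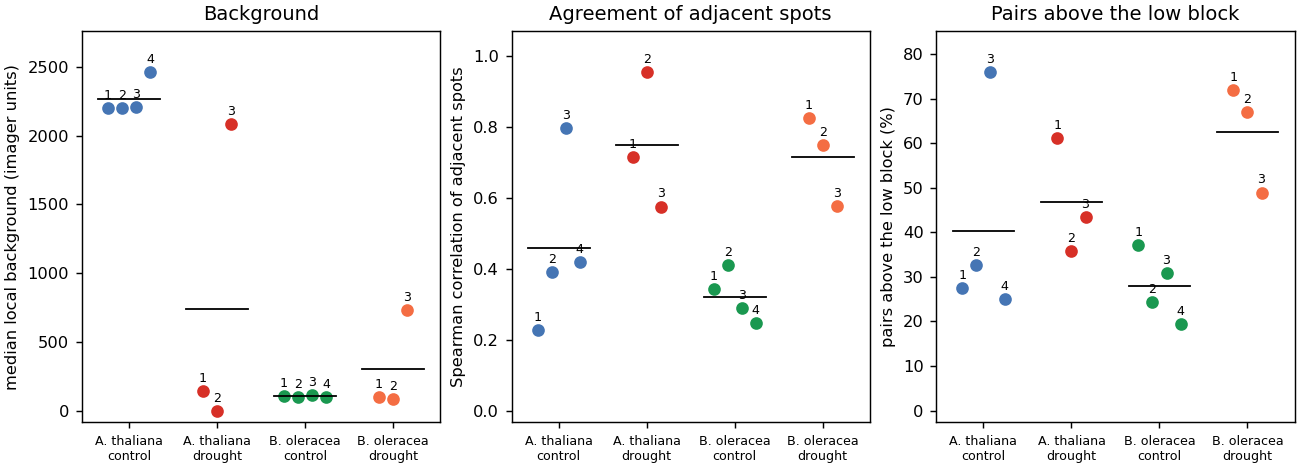
Median local background (imager units), Spearman correlation of adjacent spots and percent of pairs above the low block, 1 point per array numbered by replicate, with bars at the group means. All 4 A. thaliana controls have backgrounds of 2202 units or more and all 4 B. oleracea controls 115 units or less, and the share of pairs above the low block on B. oleracea drought arrays is 49.0% or more, against 37.2% or less on B. oleracea controls.

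**Figure D2:**
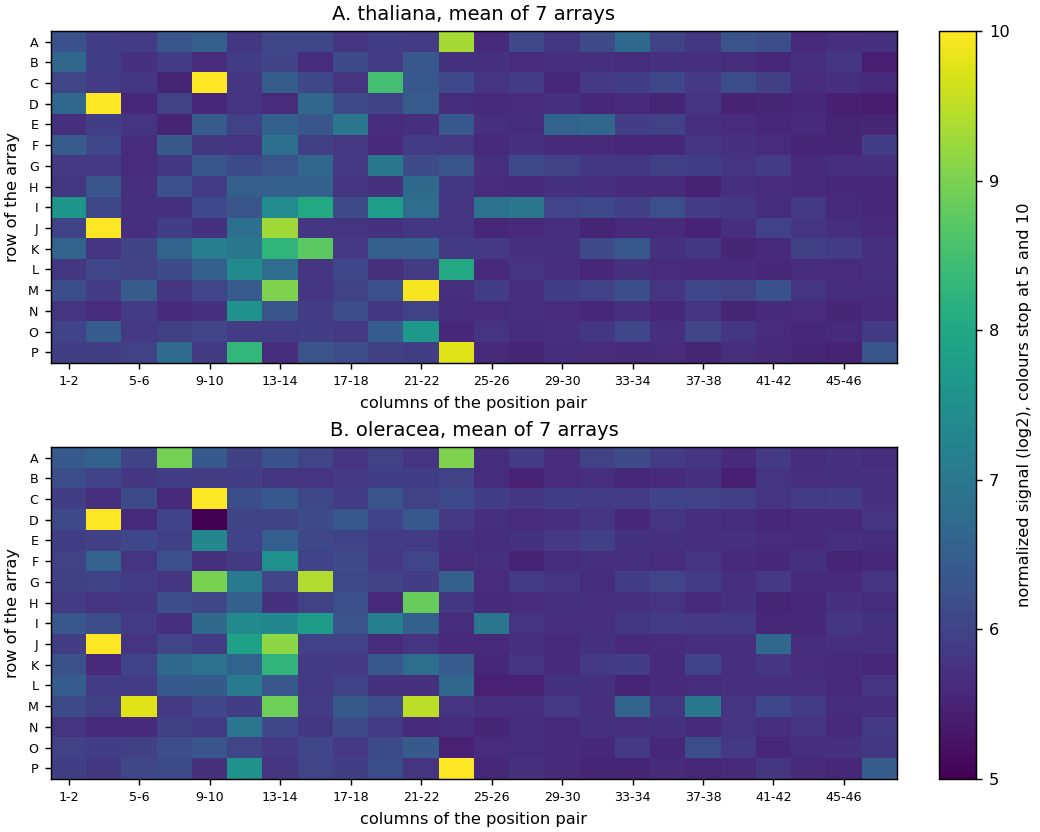
Mean normalized signal (log2) of each position pair over the 7 arrays of each species, drawn by row and column of the array, with colours that stop at 5 and 10. The even-lettered rows at columns 25 to 48 form the low block, and A7/A8 and M5/M6 are bright on the B. oleracea map while K15/K16 and C19/C20 are bright on the A. thaliana map.

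The first comparison asked which leaf transcripts drought changes in A. thaliana. The pairs with the strongest evidence were O21/O22 and G19/G20, both dimmer on the drought arrays, but neither passed the test. The signal of O21/O22 was 8.53 ± 0.96 in controls (SD, n = 4) and 6.53 ± 0.31 under drought (SD, n = 3), lower on all 3 drought arrays than on any control, a log2 change of -1.99 with an SE of 0.40 (limma adjusted p = 0.0953). That of G19/G20 was 7.88 ± 1.18 in controls (SD, n = 4) and 5.82 ± 0.17 under drought (SD, n = 3), where 1 of the 3 arrays was above the low block, so that controls were at least 3.70-fold brighter (limma adjusted p = 0.112). The 95% interval of its fitted log2 change was -3.10 to -1.01, while the bound is 1.89 log2 units. Larger falls of the mean, also short of the threshold, are given here after their values were seen. They were at L23/L24 (9.27 in controls, 6.36 under drought), K15/K16 (9.99 and 7.10) and C19/C20 (9.51 and 7.18). Control replicate 3 stood at 6.28, 7.16 and 6.65 there, within or below the range of the drought arrays.

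Across all 384 pairs, limma called 0 changed in A. thaliana. At an unadjusted p under 0.05 there were 44 pairs, 20 higher and 24 lower, where 19.2 are due by chance. All drought arrays lay on 1 side of all control arrays at 23 pairs, 5.99% of those tested, and chance gives 5.71%. The median 95% interval reached 0.47 log2 units to each side of the estimate. The count changed most with 1 array. Without control replicate 3, limma called 20 pairs, 9 higher and 11 lower, among them O21/O22, with a log2 change of -2.41, and G19/G20 (limma adjusted p = 3.65e-05 for each). Also called lower there were K15/K16 (limma adjusted p = 4.24e-08), L23/L24 (limma adjusted p = 3.69e-07) and C19/C20 (limma adjusted p = 1.91e-05). Without control 1, drought 2 or drought 3, 1 pair passed. With array weights 6 pairs passed. The background level of the image went with the groups, and 0 pairs passed with it as a block or among the arrays of high background, where drought is 1 array whose spread was taken to be that of the other groups.

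The second comparison asked the same of B. oleracea. The leading pairs that were brighter under drought were A41/A42 and M41/M42, neither of which passed the test. Both were above the low block on all 3 drought arrays and on 0 of 4 controls. The signal of A41/A42 was 6.61 ± 0.69 under drought (SD, n = 3), at least 1.36-fold above controls (limma adjusted p = 0.137). That of M41/M42 was 6.82 ± 0.32 (SD, n = 3), at least 1.57-fold above controls (limma adjusted p = 0.204). The leading pairs that were dimmer, P41/P42 (limma adjusted p = 0.137) and O43/O44 (limma adjusted p = 0.204), were above the low block on 1 and 0 of the 7 B. oleracea arrays, so no fold is given, and P41/P42 is itself a pair of the low block. The largest fitted rise in each species was also at a pair of the low block, P47/P48, with a log2 change of 1.63 and an SE of 0.55 in A. thaliana (limma adjusted p = 0.315) and 1.33 with an SE of 0.55 in B. oleracea (limma adjusted p = 0.461), named here after its values were seen. In B. oleracea it was nearly tied with A41/A42. These sizes rest on dim controls, at 5.15 to 5.79 in A. thaliana and 5.42 to 6.57 in B. oleracea. In A. thaliana the drought values were 8.87, 7.23 and 5.58, so the size rests mostly on drought 1.

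limma called 0 of the 384 pairs changed by drought in B. oleracea. At an unadjusted p under 0.05 there were 35 pairs, 21 higher and 14 lower, where 19.2 are due by chance. Drought and control arrays did not overlap at 50 pairs, 26 higher and 24 lower, which is 13% of those tested against 5.71% by chance. With no background subtraction limma called 18 pairs, all higher. Among the arrays of low background, which leaves out drought replicate 3, 2 pairs passed, and with the background level as a block 0 passed. Without drought replicate 1 the count was 2, with A41/A42 past the threshold (limma adjusted p = 0.00412), and without drought replicate 3 it was 1.

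The third comparison, the one closest to the title's question of divergence, tested whether the drought response differed between the species. limma called 1 pair, E29/E30, and chance could not be excluded for that count. The signal of E29/E30 was 7.12 ± 0.54 in A. thaliana controls (SD, n = 4) and 5.87 ± 0.53 under drought (SD, n = 3), where 1 of 3 arrays was above the low block. In B. oleracea it was 5.36 ± 0.32 in controls (SD, n = 4), with 0 of 4 arrays above the low block, and 6.44 ± 0.05 under drought (SD, n = 3), at least 1.2-fold higher. The response in B. oleracea minus that in A. thaliana was 2.32 log2 units with an SE of 0.42 (limma adjusted p = 0.0328), a size that rests on B. oleracea control signals not above the low block. It also uses 5.47 on A. thaliana drought 2, the array with a background of 0. That array read 4.86 at E37/E38, against 5.72 and 5.62 on drought 1 and 3. At A25/A26 it read 6.30, against 5.53 and 5.48. Position on the array may therefore enter its value at E29/E30, which was not tested.

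limma called no other pair for this difference, 13 of 100 relabellings of the arrays within species (the real one included) gave at least 1 call, and 25 of the 384 pairs had an unadjusted p under 0.05. O21/O22 followed, with a difference of 2.49 and an SE of 0.57 (limma adjusted p = 0.0913). It was above the low block on 2 of 4 B. oleracea controls, so that size rests partly on dim signal. P41/P42, a pair of the low block, had the same adjusted value (limma adjusted p = 0.0913). No size is given for P41/P42 because it was above the block's limit on 1 of the 14 arrays. The call of E29/E30 ended when the background level was made a block, with a difference of 2.5 and an SE of 0.55 (limma adjusted p = 0.147), and within 1 background level per species (2.4, limma adjusted p = 0.282). It ended with no background subtraction (0.43, limma adjusted p = 0.522), an offset 4 times larger (1.39, limma adjusted p = 0.0910), quantile normalization within each species (2.19, limma adjusted p = 0.0656) and cyclic loess (2.01, limma adjusted p = 0.181). It also ended without A. thaliana drought 2 or 3, any of B. oleracea controls 2, 3 and 4, or any B. oleracea drought array, with differences that stayed between 2.03 and 2.47 and a count of 0. The count was 2 without A. thaliana control 1 and 7 without A. thaliana control 3.

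**Figure D3:**
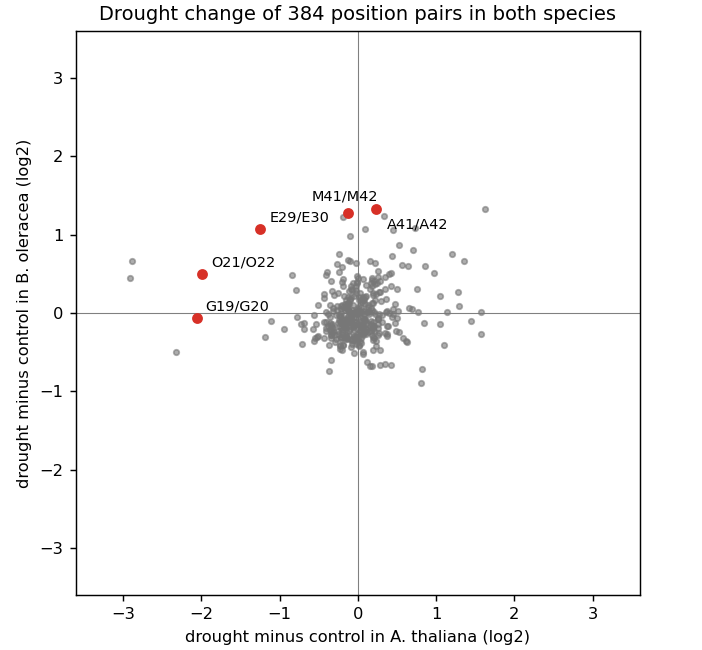
Log2 change under drought of the 384 position pairs in A. thaliana (horizontal axis) and B. oleracea (vertical axis), 1 point per pair, with 5 pairs of the text in red. The points show little relation (Pearson correlation 0.0802), and E29/E30 lies below 0 in A. thaliana and above 0 in B. oleracea.

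Across pairs, the drought changes of the species were nearly unrelated, with a Pearson correlation of 0.0802 and a Spearman correlation of 0.134, and 56.5% of pairs had the same sign. Pairs are not independent replicates, so no p is given. The Pearson correlation between the species was 0.420 with median scaling in place of quantile normalization and 0.297 with no background subtraction, so its size depended on those choices. It was -0.107 with the background level as a block. With 0 calls in each species, no overlap of calls could be tested.

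The fourth comparison set the species side by side in well-watered plants. It compares signal, not transcript level, because a probe made from one species can bind cDNA of the other less well. A7/A8 and M5/M6 were brighter in B. oleracea, and K15/K16 and C19/C20 in A. thaliana. The signal of A7/A8 was 9.33 ± 1.21 in B. oleracea (SD, n = 4) and 5.97 ± 0.20 in A. thaliana (SD, n = 4), where 1 of 4 arrays was above the low block, at least 8.85-fold brighter in B. oleracea (limma adjusted p = 0.00588). That of M5/M6 was 9.60 ± 1.21 against 6.32 ± 0.37 (SD, n = 4 each), with 2 of 4 A. thaliana arrays above the low block, at least 9.11-fold brighter in B. oleracea (limma adjusted p = 0.0282). The 95% interval of the fitted log2 difference was 2.08 to 4.64 at A7/A8 and 1.69 to 4.88 at M5/M6. Both intervals reach below the bounds, which are 3.15 and 3.19 on the log2 scale.

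K15/K16 was above the low block on 4 of 4 A. thaliana controls and 0 of 4 B. oleracea controls. Its signal of 9.99 ± 1.90 in A. thaliana (SD, n = 4) was at least 14.1-fold above that in B. oleracea (limma adjusted p = 0.00346), a bound that was 27.1-fold without control replicate 3, 10.4-fold without control 1 and 1.99-fold on control 3 alone. The 95% interval of its fitted log2 difference was -5.84 to -3.03, while the bound is 3.82 log2 units. C19/C20 had a signal of 9.51 ± 2.00 in A. thaliana and 6.51 ± 0.23 in B. oleracea (SD, n = 4 each), a log2 difference of -2.99 with an SE of 0.69 (limma adjusted p = 0.0286). The wide SDs of the A. thaliana values came with control replicate 3, which stood at 7.16 for K15/K16 and 6.65 for C19/C20, while the other 3 controls lay between 10.6 and 11.3 and between 9.87 and 11.3. Before normalization control 3 was not dim in imager units at these pairs. At K15/K16 its signal over background was 1142 units, against 754 to 813 on the other controls. At C19/C20 it was 656 units, against 604 to 771. Both values were low for that array, whose spots had a 95th percentile of 2088 units over background, against 146 to 176 on the other controls.

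limma called 15 of the 384 pairs between the species in control plants, 6 brighter and 9 dimmer in B. oleracea, and 60 had an unadjusted p under 0.05. Of the 6, 5 were above the low block on all 4 B. oleracea controls, and the other, P41/P42, is a pair of the low block. All 9 were above it on the 4 A. thaliana controls, and 4 of them on 0 of the B. oleracea controls. The count was 5 without A. thaliana control 2 or control 4, 9 without B. oleracea control 2 and 7 without B. oleracea control 3. M5/M6 lost its call without A. thaliana control 1, 2 or 4 or B. oleracea control 3 or 4, and C19/C20 without A. thaliana control 1, 2 or 4 or any B. oleracea control. With median scaling limma called 12 pairs, 0 brighter and 12 dimmer in B. oleracea. With quantile normalization within each species it called 360, 2 brighter and 358 dimmer, with a median difference (B. oleracea minus A. thaliana) of -1.27 log2 units over all pairs. With cyclic loess it called 0, and K15/K16 (limma adjusted p = 0.0617) and A7/A8 (limma adjusted p = 0.146) lost their calls. All 4 A. thaliana controls had a high background and all 4 B. oleracea controls a low one, so species and background cannot be told apart among the control arrays. With the background level as a block, which then rests on the drought arrays, 0 pairs passed. C19/C20 then had a difference of -3.38 with an SE of 1.13 (limma adjusted p = 0.351), against -2.99 with an SE of 0.69 before, and A7/A8 a fitted difference of 2.2 with an SE of 0.88 (limma adjusted p = 0.589), against 3.36 with an SE of 0.59. The lost calls came with wider errors and, at A7/A8, a smaller difference, so they do not show that background accounts for the differences.

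**Figure D4:**
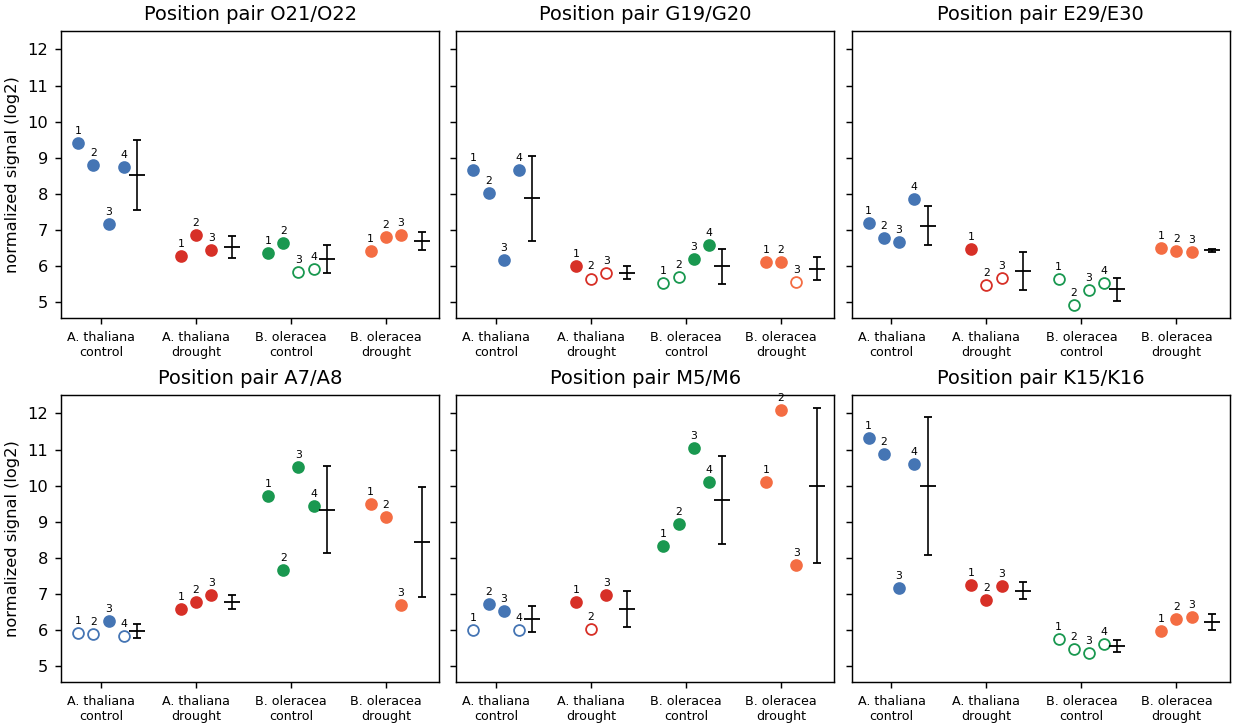
Normalized signal (log2) of 6 position pairs on each array, numbered by replicate, filled where the pair was above the low block and open where it was not, with the mean and SD of each group as bars. On this normalized scale A. thaliana control 3 lies below the other 3 controls at O21/O22, G19/G20 and K15/K16, and B. oleracea drought 3 lies below the other B. oleracea arrays at A7/A8 and M5/M6. Before normalization the signal of control 3 over background was not the lowest of the A. thaliana controls at any of the pairs named for it. Its signal was higher over the whole array, with a median of 103 units over background, against 9.94 to 17.5 on the other controls.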

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

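The tests of replicates 3 below, and the counts of splits for drought within each species, were chosen after the results they bear on had been seen. The counts of splits for the difference of the responses and for the species in control plants, and the test of duplicate agreement among control arrays, were set down before their results were seen.

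In 30 sets of 4 control arrays (4 array measures and 11 named position pairs in each species), 3 values stood far from the rest of their group, where chance gives about 1.5. A. thaliana control 4 had a median background of 2465 units, against 2202 to 2213 on the other 3 controls. A. thaliana control 3 had a median signal over background of 103 units, against 9.94 to 17.5 on the other 3. It also had 76.0% of pairs above the low block, against 25% to 32.6%. The drought change of E29/E30 differed between the species by 2.32 log2 units (B. oleracea minus A. thaliana, limma adjusted p = 0.0328), a fitted size that rests on B. oleracea controls above the low block on 0 of 4 arrays and A. thaliana drought on 1 of 3, and the call was lost in 14 of 30 alternatives.

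A. thaliana control 3 looked more like the drought arrays than like the other controls. Its correlation with them, corrected for the agreement of the spots of a pair, exceeded that with the other 3 controls by 0.200 on average (95% bootstrap interval over pairs 0.107 to 0.298), and by 0.242 (interval 0.148 to 0.350) without drought 2, whose spots agreed in the low block too, which argues against lower precision of the other controls as the whole cause. These gaps include control 1, where D3/D4 (4.82) and J3/J4 (5.46) were dim, against 9.55 to 11.8 and 9.91 to 11.5 on the other arrays. Control 3 correlated at 0.541 with control 1, against 0.795 and 0.738 with controls 2 and 4. With drought 1 to 3 it correlated at 0.927, 0.807 and 0.939. Part of the gap therefore comes from control 1, and without that array the gap is smaller but above 0. No interval was computed for it. A wrong label stays open, since the lowest corrected correlation with a drought array exceeded the highest with a control by 0.0121 (interval -0.112 to 0.120) and by 0.132 (interval 0.0364 to 0.242) without drought 2, so the separation depends on that array. A difference in the water status of the plants behind control 3 may also account for it and was not tested. The resemblance was not to drought arrays alone. Corrected correlations of control 3 with B. oleracea controls 1 to 4 were 0.818, 0.828, 0.706 and 0.697. At 7 pairs controls 1, 2 and 4 all lay over 1 log2 unit above control 3. There the A. thaliana drought arrays differed from control 3 by 0.0951 on average and the B. oleracea controls by -0.279. The low normalized levels of control 3 at O21/O22 and G19/G20 are relative to a higher signal over the whole array. At O21/O22 its signal over background was 1132 units, against 292 to 323 on the other controls. At G19/G20 it was 281 units, against 218 to 317.

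B. oleracea drought 3 stood between the species. On the 5 pairs that were called brighter in B. oleracea controls and lay above the low block on all 4 of them, its score was 0.287, where 0 is the A. thaliana control mean and 1 the B. oleracea control mean, against 0.199 to 0.297 on A. thaliana drought arrays and 1.11 or more on B. oleracea drought 1 and 2. On the 9 pairs called brighter in A. thaliana controls its score was 0.902, against 0.879 and 0.819 on B. oleracea drought 1 and 2 and 0.630 to 0.904 on A. thaliana drought arrays. At 5 of the 9 it lay below all 7 A. thaliana arrays, which goes against an A. thaliana array under this label, but A. thaliana drought 2 lay below the other 6 at 7 of the 9, so that, or a part of A. thaliana RNA, stays open. Its corrected correlation with the 3 A. thaliana drought arrays exceeded that with B. oleracea drought 1 and 2 by 0.0643 on average (interval 0.00185 to 0.113), and by 0.108 (interval 0.0498 to 0.164) without A. thaliana drought 2, which argues, narrowly with all 3, against low precision of this array alone, while a real fall of transcripts in this sample stays open as untested. Its corrected correlations were 0.771 to 0.893 with the B. oleracea controls and 0.508 to 0.880 with the A. thaliana controls. A. thaliana drought 3 had a like pattern (0.784 to 0.904 and 0.583 to 0.939), so this does not tell the species apart.

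Drought changes followed the signal on arrays of the other species. Across pairs, the Spearman correlation with the mean level on the other species' arrays was 0.457 for B. oleracea and 0.325 for A. thaliana, and pairs are not independent replicates. Lower precision of control arrays may give this. Over the 8 control arrays, duplicate agreement went with each array's rank correlation to the other species' mean level (Pearson 0.949, exact permutation p = 0.00402, Spearman 0.786, exact permutation p = 0.0279). Within species r was 0.987 in A. thaliana controls and 0.541 in B. oleracea controls (n = 4 each, 3 relations computed). Without the 2 arrays farthest from the median agreement, r was 0.609 (n = 6, exact permutation p = 0.204), so the relation rests on those arrays, one of them A. thaliana control 3. A less precise array follows any level profile less closely, so this relation is due whatever causes the pattern. It cannot decide for lower precision, and a response to drought shared by the species stays open as untested.

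Other splits of the arrays were counted. For drought, the real count was 0 in each species, which all 35 of 35 splits reach by necessity, so this says nothing about chance. The highest other count was 24 in A. thaliana, from the split that sets controls 1, 2 and 4 against the other 4 arrays and so points to a structure of the arrays other than the labels. It was 6 in B. oleracea. For the difference of the responses, 13 of 100 relabellings within species, the real one included, gave at least 1 call, and the highest other count was 23, so chance could not be excluded. For the species in control plants, 1 of 35 splits gave 15 calls, the real one, with 8 as the highest other count. That is the smallest share that 35 splits can give, so it argues against chance without excluding it. Background and species are not told apart there.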

How the results depend on the processing

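Of the alternatives here, the background level, array weights, leaving out A. thaliana control 3 with B. oleracea drought 3, the filter at the low block and the low block without P47/P48 were chosen after the data were seen. No change at a named position pair reversed, while the A. thaliana drought difference in the share of pairs above the low block (6.48 percentage points) fell to -0.694 without drought 1, and the correlation of the responses changed sign in 3 alternatives below. Over the 13 results named for a position pair (11 pairs), 333 of 388 alternatives kept direction and side of the threshold, 39 lost a call and 16 gained one. Only results that had passed could lose a call. E29/E30 lost it in 14 of 30 alternatives, and of 29 each M5/M6 lost it in 11, C19/C20 in 9, A7/A8 in 3 and K15/K16 in 2. For the results that had not passed, keeping the side means staying short of the threshold. Counts of limma calls are given in the order A. thaliana drought, B. oleracea drought, difference of the responses, species in controls, against 0, 0, 1 and 15. Causes were not tested.

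They were 0, 18, 7 and 31 with no background subtraction, 0, 1, 3 and 32 with local background subtracted and floored at the offset, 0, 0, 0 and 14 with an offset 4 times larger, and 0, 0, 1 and 16 with one 4 times smaller. Median scaling gave 0, 1, 2 and 12, quantile normalization within species 0, 0, 0 and 360 (it leaves the median shift of -1.27 in), cyclic loess 0, 0, 0 and 0, and the values of the deposited table gave 0, 0, 2 and 18. Trend and robust variance gave 0, 1, 1 and 16, and each spot on its own 0, 0, 0 and 33 of 768. The background level as a block gave 0, 0, 0 and 0, and arrays of 1 background level 0, 2 and 0 for the first 3. Array weights gave 6, 1, 4 and 17, and leaving out both arrays 20, 1, 13 and 24. A filter on the dimmest pairs gave 0, 0, 1 and 15 and the low block filter 0, 0, 1 and 14. Fitting each species alone gave 0 and 0. The correlation of the responses moved from 0.0802 to 0.297 with no background subtraction, 0.420 with median scaling and -0.107 with the background block.

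Leaving out 1 array at a time gave 0 to 20, 0 to 2, 0 to 7 and 5 to 21 calls, and correlations of -0.00190 to 0.140. The 20 and the 7 came without A. thaliana control 3. E29/E30 lost its call in 14 of 30 alternatives, with limma adjusted p from 0.00173 to 0.522.

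The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.0145, 0.0620 and 0.0634 in A. thaliana and 0.0390, -0.240 and -0.318 in B. oleracea. With the replicate block the counts were 0, 0 and 1, the correlation of the responses was -0.0297, and a replicate block across species gave 10 for the species in controls. Not every array correlated best with its own number.

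Not run for want of gene names or named blanks were the housekeeping scaling, the gene list tests (camera, with preset and estimated correlation, and fry) and levels from blank spots, for which the low block stood in. A replicate block within species leaves no estimate for the species in controls. The low signal over background, with 27 to 123 of 288 pairs above the low block on every array of a group, limits which pairs can show a change.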

Other observations

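Outside the low block, 13 of 288 pairs were above it on all 14 arrays and 11 on none. No pair was above it on all 7 arrays of one species and on no array of the other. The 13 pairs had a mean normalized signal of 8.69 on the log2 scale, against 6.05 for the other pairs. Under drought, 10 of the 13 were higher in A. thaliana, with a median log2 change of 0.82 and a median SE of 0.48, and 4 of the 13 were higher in B. oleracea, with a median change of -0.14. None of the 13 passed the test in either species, with a smallest limma adjusted p of 0.262 in A. thaliana and 0.393 in B. oleracea. These pairs were chosen after their values were seen, and which genes they hold is not given in the sources used here.

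The lowest volume flagged present was 27.9 to 28.0 units on A. thaliana controls 1, 2 and 4, 27.4 units on B. oleracea drought 1 and 2, and 448 units on A. thaliana control 3. It was 113 and 251 units on A. thaliana drought 2 and 3, and 0.03 units or less on A. thaliana drought 1 and the B. oleracea controls. On B. oleracea drought 3 the lowest flagged volume was 16.6 units and the highest unflagged one 29.7 units, so no single volume set the flag there.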
